A study of Mus musculus with 41 samples.

How the data were processed

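Total RNA from the spleens of C57BL mice was profiled on a one-channel miRNA microarray after conversion to biotin-labelled first strand cDNA, per the labels. The 41 arrays form 8 groups, given by 4 genotypes with a control and a C. parvum group each. The genotypes are wild type (WT), NOS2 knockout (NOS2KO), p53 knockout (p53KO) and a double knockout of both genes (DKO). The series design text speaks of 4 or 5 mice per group and does not mention the double knockout, whose groups hold 6 arrays each in the labels. The scanner, the background correction and the normalization are not given in the sources used here.

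The authors deposited 1 table of processed log2 values with 637 probe rows for 41 arrays. The base of the logarithm is not stated in the table or the labels and was inferred from the values, whose maximum is 16.9. That maximum lies above the ceiling of a 16-bit scanner on a log2 scale, so the inference is not secure. If the base differs, every log2 change and fold given here differs with it. Of 26117 cells, 10562 (40.4%) hold no value, and 227 probes have a value on all 41 arrays. A missing cell was mostly a dim one. In the median array, 0.931 of pairs of a measured and a missing cell ranked the measured one higher by the probe's mean on the other arrays. Probe names end in -a (397 rows), -p (236 rows) or otherwise (4 rows). The meaning of these endings is not given in the sources used here, so probes of a miRNA were kept apart. A name without an ending stands for the -a probe. The arm of a miRNA is given only where the probe name states it. RefSeq names of mouse genes were found for 591 rows, and miR-801 is listed there as Rnu11, the U11 small nuclear RNA. No coordinates were used.

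Array medians over the 227 common probes ranged from 9.87 to 10.6, a spread of 0.705 that exceeded the limit of 0.5 set for using the values as deposited. Quantile normalization between arrays was therefore applied. Arrays with missing cells were ranked from the brightest value down, with missing cells placed below all measured ones and left missing. Changes are therefore relative to the bulk of the probes, and a uniform shift of all miRNAs would not be seen. As deposited, the array medians over the common probes were lower after treatment, on average 10.19 in control and 9.90 in treated WT arrays. They were 10.30 and 10.01 in NOS2KO, 10.49 and 10.15 in p53KO, and 10.19 and 10.13 in DKO. Normalization largely removed this fall, so the balance of rises and falls depends on it. The choices of test, list members, named miRNAs and most alternatives were made before the data were examined.

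All 8 group means were fitted by least squares per probe with limma 3.58.1 in R 4.3.3, with moderated variances and Benjamini-Hochberg adjustment within each comparison at 0.05. A probe was tested where each group of the comparison had at least 3 measured values. Errors of changes are standard errors (SE), and errors of group means are standard deviations (SD). The comparisons were the effect of C. parvum in each genotype, its equal-weight mean over the genotypes, each knockout against WT among controls and among treated mice, and the difference of each knockout's treatment effect from that of WT. The named miRNAs are the 10 largest rises and 10 largest falls past the threshold in each treatment effect (5 of each elsewhere, 1 probe per miRNA), 15 preset miRNAs, and up to 4 members of each list with the smallest p. Where none passed, the 3 smallest p were taken.

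Lists were fixed for p53-responsive miRNAs, the miR-34, miR-29 and let-7 families, the miR-17-92 cluster with its paralogs, inflammation (NF-kB), hypoxia, the cell types myeloid, lymphoid, erythroid, progenitor with megakaryocyte and stromal with smooth muscle, and the tissues pancreas, liver, nervous system and striated muscle. Each miRNA was represented by its brightest probe. Lists with at least 3 tested members were tested with limma's camera on the moderated statistics, with a preset correlation between members of 0.01 and with an estimated one. The estimated correlation left 0 of the 13 list calls past the threshold.

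The procedure was tested on simulated data, 20 sets per comparison with the spread and the missing cells of the table. For the treatment effect in WT it recovered 25.1% of changes of 0.5 log2 units and 75.7% of changes of 1, with 3.7% false calls. For the interaction of p53KO it recovered 7.28% and 43.9%. For the treatment effect in DKO, false calls were 9.84%, above the nominal 5%, and 4.83% when arrays were only centred on their medians. Normalization reduced simulated changes to between 0.938 and 0.981 of their size. The simulated probes were independent of each other, no array set was simulated, and changes were placed only in probes measured on most arrays. The shares recovered therefore do not cover sparsely measured probes. The shares of false calls do not cover an effect of the array sets described below. A first requirement on recovery was not met and was replaced by one on the bias of the fit, and several forms of normalization were compared, both after results had been seen.

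The arrays separate into sets that no label names, found after the data were examined. The miR-370 probe read at most 9.32 on 18 arrays (set 1) and at least 11.1 on the other 23 (set 2), with no array between. Each comparison was repeated with the set as a block and, where possible, within a set. No depth applies to arrays, and the number of arrays limits the precision. Replicate numbers do not pair the arrays. The alternatives tried were the values as deposited, median centring, a floor, dim probes left out, array weights, a variance trend, 1 value per miRNA, only the arrays compared, the replicate number as a block, contrasts averaged over the other gene, each array left out in turn, missing cells set to a low value, the 227 common probes, another quantile routine, and leaving out WT control 2 with NOS2KO C. parvum 5. The last 4 and the array sets were added after seeing the data. Keeping rows of other organisms was not run, since every row names a mouse probe. The knocked-out genes are not measured on a miRNA array, so the genotype labels could not be checked on the target.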

Results

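Spleen miRNA levels were measured on 41 arrays to compare mice treated with C. parvum, a bacterial preparation that provokes inflammation, with saline controls in 4 genotypes. There were 5 control and 5 treated WT arrays, 5 and 5 NOS2KO arrays, 4 and 5 p53KO arrays, and 6 and 6 DKO arrays. NOS2 encodes the inducible nitric oxide synthase of activated macrophages, and p53 is the tumour suppressor Trp53. An array gave values for 310 to 464 of the 637 probes. Levels are normalized log2 signals. Arrays of set 1 were all 10 WT arrays, NOS2KO C. parvum 1 and 2, DKO controls 1 to 5 and DKO C. parvum 6, and the other 23 formed set 2. Of 291 probes tested for the set within groups, 44 differed (30 higher in set 2, 14 lower). The treatment effect of WT lay within set 1 and that of p53KO within set 2, while NOS2KO and p53KO controls shared no set with WT controls.

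**Figure D1:**
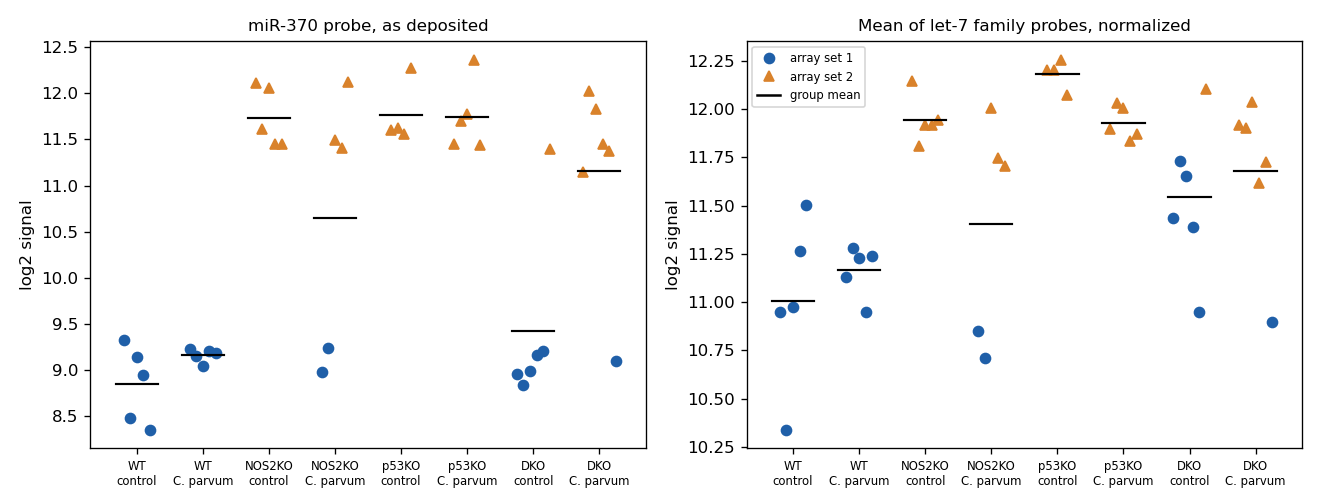
Left, log2 signal of the miR-370 probe as deposited on each of the 41 arrays by group. Right, mean normalized log2 signal of the let-7 family probes on the same arrays. Circles are set 1, triangles set 2, and lines are group means. No array lies between 9.32 and 11.1 for miR-370, and DKO control 6 and DKO C. parvum 6 each lie with the other set than the rest of their group.

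The treatment effect in WT asked which miRNAs C. parvum changed in the spleen of mice with both genes. The largest rise was in the erythroid miRNA miR-486, from 12.10 ± 0.53 (SD, n = 5) in controls to 14.45 ± 0.17 (SD, n = 5), a change of 2.35 ± 0.39 (SE) and a fold of 5.08 (adjusted p = 1.38e-05, all 5 treated arrays above the control mean). Erythroid miR-451 rose by 1.72 ± 0.33 (SE), from 11.56 ± 0.38 to 13.29 ± 0.35 (SD, n = 5 each). miR-222, a regulator of proliferation in blood and vessel cells, rose by 1.42 ± 0.23. miR-21, which inflammatory signals induce in many tissues, rose by 0.89 ± 0.21, and miR-223, the abundant miRNA of granulocytes and monocytes, rose by 0.70 ± 0.19. Other rises were those of the -p probes of miR-672 (1.47) and miR-705 (1.17) and of miR-7-2 (1.34), miR-412 (1.21), miR-700 (1.15), miR-448 (1.15) and miR-326 (1.13).

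The falls in WT were led by miR-699, from 10.51 ± 0.27 to 8.27 ± 0.56 (SD, n = 5 each), a change of −2.24 ± 0.30 (SE, adjusted p = 6.76e-07). miR-703 fell by 1.75 ± 0.34. miR-181a-5p and miR-181c, which act in lymphocyte development, fell by 1.49 ± 0.19 and 1.49 ± 0.22. miR-99a and miR-100, members of the progenitor and megakaryocyte list, fell by 1.56 ± 0.26 and 1.24 ± 0.27. miR-145, typical of smooth muscle, fell by 1.28 ± 0.19, and miR-215, a p53-responsive miRNA, fell by 1.25 ± 0.28. miR-138 (−1.29) and the -p probe of miR-669c (−1.27) also fell. miR-34a, a direct transcriptional target of p53, fell by 1.12 ± 0.32 (adjusted p = 0.00543), to a dim level of 6.56 ± 0.34 (SD, n = 5).

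All 3 tested members of the miR-29 family fell in WT, and 3 of 3 did so adjusted over the list alone. miR-29a changed by −1.08 ± 0.17, miR-29b-2 by −0.98 ± 0.15 and miR-29c by −0.90 ± 0.20 (SE). The list passed camera (adjusted p = 0.00294), and its adjusted p was 0.168 with an estimated correlation. The -p probes of the family moved the other way for miR-29a (0.55) and miR-29c (0.73). Of 12 progenitor and megakaryocyte members, 7 fell, 0 rose and 5 did not pass, against 9 falls and 1 rise adjusted over the list alone (adjusted p = 0.0109, and 0.292 with an estimated correlation). Inflammation-related miR-155 (−0.23 ± 0.23, adjusted p = 0.457) and miR-146a (0.00 ± 0.16, adjusted p = 0.991) did not pass. Lymphocyte miR-150 gave −0.63 ± 0.28 (adjusted p = 0.0743).

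In WT, 110 of 319 tested probes passed, 55 higher and 55 lower. The calls split 40 higher and 71 lower as deposited, where the median change was −0.06, and 79 higher and 49 lower after median centring. All 10 arrays belong to set 1. When the set was a block, the count was 117, which held all 110 calls, and within set 1 it was 120, sharing 104. Both fits leave the changes in WT as they were and alter only the spread, so they do not check the set.

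**Figure D2:**
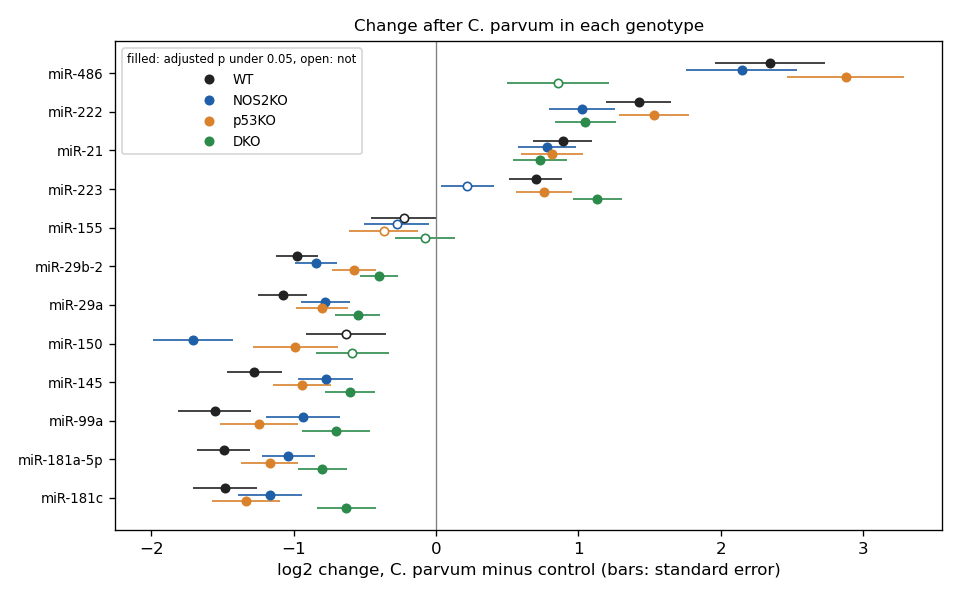
Change of 12 miRNA probes after C. parvum in each genotype, on the horizontal axis as log2 change with standard errors. Filled circles passed an adjusted p of 0.05 and open circles did not. miR-486 changed by 2.35 in WT, 2.15 in NOS2KO and 2.88 in p53KO, and gave 0.85 without passing in DKO, while miR-21 passed in every genotype.

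In NOS2KO mice the same comparison asked what C. parvum changes without inducible nitric oxide synthase. miR-486 rose from 12.09 ± 1.01 to 14.23 ± 0.45 (SD, n = 5 each), by 2.15 ± 0.39 (SE, adjusted p = 0.000146). Lymphocyte miR-150 fell from 15.27 ± 0.17 to 13.56 ± 0.84 (SD, n = 5 each), by 1.71 ± 0.28 (SE). miR-329, encoded in the Dlk1-Dio3 imprinted cluster, rose by 1.71 ± 0.34, miR-7-2 by 1.27 ± 0.23, miR-702 by 1.23 ± 0.22 and miR-222 by 1.03 ± 0.23. miR-9-3-5p, which inflammatory signals induce in myeloid cells, rose by 1.19 ± 0.23, and miR-497 of the stromal list by 1.02 ± 0.17. The -p probes of miR-671 (1.26), miR-323 (1.05) and miR-451 (1.0) rose. Falls were found for miR-181c (−1.17), miR-703 (−1.13), smooth muscle miR-143 (−1.09), miR-199a*-1-3p (−1.26), let-7f-1 (−1.19) and the -p probes of miR-296 (−1.5), miR-221 (−1.36), miR-123 (−1.31) and miR-297b (−1.23). miR-296 lost its call with the set as a block (−1.18 ± 0.53, adjusted p = 0.113).

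The miR-29 family fell in NOS2KO in 3 of 3 members, also adjusted over the list alone, with a median change of −0.84 (adjusted p = 0.00121, and 0.11 with an estimated correlation). miR-29a changed by −0.78 ± 0.17 and miR-29c by −0.98 ± 0.20. miR-21 rose by 0.78 ± 0.21 and miR-145 fell by 0.77 ± 0.19. The changes of miR-223 (0.22 ± 0.19, adjusted p = 0.399), miR-451 (0.83 ± 0.34, adjusted p = 0.0632) and miR-34a (−0.83 ± 0.34, adjusted p = 0.0648) did not pass. Given the set block, miR-451 passed at 1.21 ± 0.31 (adjusted p = 0.00574). Of 346 probes, 89 passed, 42 higher and 47 lower, against 25 higher and 70 lower as deposited and 68 higher and 34 lower after median centring. Given the set block, 66 passed, 60 of them shared, and within set 2 (5 controls, 3 treated) 59 passed, 49 of them shared. With only the arrays compared 47 passed.

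In p53KO mice the comparison asked what C. parvum changes without p53. miR-486 rose from 10.96 ± 0.63 (SD, n = 4) to 13.83 ± 1.09 (SD, n = 5), by 2.88 ± 0.41 (SE) and a fold of 7.35 (adjusted p = 4.36e-06). The erythroid miRNAs miR-144 and miR-451 rose by 1.49 ± 0.41 and 1.36 ± 0.35. miR-222 rose by 1.53 ± 0.25, miR-21 by 0.81 ± 0.22 and miR-223 by 0.76 ± 0.20. Rises were also found for miR-207 (1.18), miR-483 (1.15), miR-700 (1.09), miR-485-3p (1.08), miR-329 (1.06) and the -p probe of miR-503 (1.39). miR-699 fell by 1.67 ± 0.31, miR-181c by 1.34 ± 0.24, miR-99a by 1.24 ± 0.27, miR-181a-5p by 1.17 ± 0.20, miR-143 by 1.06 ± 0.26 and miR-150 by 0.99 ± 0.30. Further falls were those of miR-703 (−1.16), miR-139 (−1.03), the miR-24-2 a/p probe (−1.10) and the -p probes of miR-297b (−1.5) and miR-669a (−1.04).

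The miR-29 family fell in p53KO in 3 of 3 members, also adjusted over the list alone, with a median of −0.80 (adjusted p = 0.0108, and 0.221 with an estimated correlation). Of 12 progenitor and megakaryocyte members 5 fell, 7 adjusted over the list alone, and none rose (adjusted p = 0.0108, and 0.264 with an estimated correlation). miR-34a gave −0.75 ± 0.34 (adjusted p = 0.0833) and did not pass. Of 324 probes, 94 passed, 45 higher and 49 lower, against 31 higher and 68 lower as deposited and 85 higher and 31 lower after median centring. The median change as deposited was −0.15. Within set 2, which holds all 9 arrays, 104 passed, 92 of them shared, and with the set as a block 102 passed, including all 94. Here too these fits alter only the spread and do not check the set. Without p53KO C. parvum 1 the count was 62.

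In DKO mice the comparison asked what C. parvum changes without either gene. Myeloid miR-223 rose from 14.17 ± 0.12 to 15.31 ± 0.33 (SD, n = 6 each), by 1.13 ± 0.17 (SE, adjusted p = 3.38e-05), and still passed with the set as a block (0.77 ± 0.18, adjusted p = 0.0117). The abundant miR-26a-2 fell by 0.66 ± 0.13, and by 0.64 ± 0.16 with the block (adjusted p = 0.0134). miR-218 rose by 1.28 ± 0.31 and the -p probe of miR-496 by 1.37 ± 0.41, and both also passed with the block (adjusted p = 0.0294 and 0.043). miR-181a-5p fell by 0.80 ± 0.17, miR-181c by 0.63 ± 0.21, miR-99a by 0.70 ± 0.24, miR-126*-5p by 0.67 ± 0.15 and miR-145 by 0.60 ± 0.18, while miR-21 rose by 0.73 ± 0.19. None of these 6 passed with the block, where their changes were −0.59, −0.53, −0.63, −0.54, −0.45 and 0.42. The erythroid miRNAs did not pass, with 0.85 ± 0.36 for miR-486 (adjusted p = 0.112), −0.12 ± 0.31 for miR-451 and 0.09 ± 0.35 for miR-144.

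The DKO comparison is almost parallel to the array sets, with 5 controls and 1 treated array in set 1 and 1 control and 5 treated arrays in set 2. Several of its largest changes shrank or turned with the set as a block. miR-370 gave 1.71 ± 0.42, and 0.12 ± 0.22 with the set as a block. The -p probe of miR-686 gave −3.19 ± 1.07, and 0.20 ± 0.41 with the block. The -p probe of miR-326 gave 2.58 and 0.18 with the block, that of miR-687 2.37 and 0.39, and miR-429 gave 1.44 and −0.11. Changes of miR-205 (1.5), striated muscle miR-1 (1.46), miR-135a-1 (1.26), the -p probe of miR-293 (1.63), miR-720 (−1.10), miR-455-3p (−1.03), the miR-24-2 a/p probe (−0.76) and miR-203 (−0.72) also lost their calls with the block. Of 377 probes 53 passed, 30 higher and 23 lower, against 18 higher and 9 lower as deposited and 31 higher and 9 lower after median centring. With the set as a block 11 passed, all among the 53, with 1 call within set 1 and 2 within set 2. Array weights gave 129. The count was 26 without DKO control 3, 27 without control 4, 31 without C. parvum 2 and 35 without C. parvum 5. miR-29a (−0.55 ± 0.16) and miR-29b-2 (−0.40 ± 0.13) fell and miR-29c (−0.22 ± 0.18) did not pass, and the family list gave an adjusted p of 0.0993. miR-29b-2 kept its call with the block (−0.60 ± 0.15, adjusted p = 0.0201). The miR-34 family, tested here with 3 members, had no call, a median of −0.62 and an adjusted p of 0.28.

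The mean treatment effect asked which changes hold on average over the 4 genotypes. Erythroid miR-486 rose by 2.06 ± 0.19 (SE, a fold of 4.16, adjusted p = 4.17e-11) and miR-451 by 0.95 ± 0.16. miR-222 rose by 1.26 ± 0.11, miR-21 by 0.80 ± 0.10 and miR-223 by 0.70 ± 0.09. miR-329 (1.05), miR-7-2 (0.87), miR-702 (0.87) and the -p probes of miR-101b (0.90), miR-705 (0.82) and miR-672 (0.80) rose. The largest falls were those of miR-699 (−1.26 ± 0.15), miR-181c (−1.15 ± 0.11), miR-181a-5p (−1.12 ± 0.09), miR-99a (−1.11 ± 0.13), miR-150 (−0.98 ± 0.14), miR-145 (−0.90 ± 0.10) and miR-100 (−0.86 ± 0.13). miR-703 (−0.98), miR-500 (−0.97) and the -p probe of miR-297b (−0.96) also fell. The p53 target miR-34a fell by 0.83 ± 0.16 on average (adjusted p = 2.89e-05), while miR-155 (−0.24 ± 0.11, adjusted p = 0.0707) and miR-146a (0.12 ± 0.08, adjusted p = 0.175) did not pass. The miR-34a probe was dim in treated mice, with 6.56 ± 0.34 (SD, n = 5) in WT and 6.61 ± 1.01 (SD, n = 4) in NOS2KO. These levels lie near 5.87, the low value used for missing cells, and with the floor its change in NOS2KO was 0.086. Without treatment, miR-34a was not called lower in p53KO (0.18 ± 0.34, adjusted p = 0.705) or DKO (0.42 ± 0.31, adjusted p = 0.394) than in WT. Nor did its response in p53KO pass as different from that in WT (0.37 ± 0.46, adjusted p = 0.941). A dependence of its fall on p53 is therefore not shown.

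By list, all 3 miR-29 members fell (median −0.73, adjusted p = 0.00249, and 0.154 with an estimated correlation). The separate probes miR-29b-1 (−0.76) and miR-29b (−0.85) fell too, while the -p probes of miR-29a (0.43), miR-29b-2 (0.34) and miR-29c (0.51) rose. Of 12 progenitor and megakaryocyte members 7 fell, among them miR-10b (−0.58) and miR-126*-5p (−0.53), and 1 rose (adjusted p = 0.0175, and 0.274 with an estimated correlation). Of 5 lymphoid members 3 fell and 2 rose (adjusted p = 0.248). miR-181b-2 fell by 0.73 ± 0.09, and the list counts miR-181a through its -p probe, which rose by 0.67 ± 0.12 while miR-181a-5p fell. Of 4 myeloid members miR-223 and miR-27a (0.35) rose and miR-24-1-3p (−0.45) and miR-23a (−0.38) fell (adjusted p = 0.921). Of 3 erythroid members 2 rose (adjusted p = 0.174), and of 7 inflammation members miR-21, miR-9-3-5p (0.75) and miR-212 (0.55) rose and none fell (adjusted p = 0.334).

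Among 10 p53-responsive members 2 rose, among them miR-22 (0.62 ± 0.11), and 4 fell, among them miR-192 (−0.42 ± 0.08), miR-145 and miR-34a (adjusted p = 0.469). Of 5 stromal members miR-497 (0.68 ± 0.09) rose, miR-145 and miR-214 (−0.30 ± 0.08) fell and 2 did not pass (adjusted p = 0.644). The miR-17-92 list had 1 fall, of miR-19b-1 (−0.40 ± 0.13), among 9 members (adjusted p = 0.999). No let-7 member of 8 passed (adjusted p = 0.654), but with the set as a block 3 of 8 passed as falls, let-7f-2 (−0.36 ± 0.11, adjusted p = 0.00319), let-7g (−0.24 ± 0.07, adjusted p = 0.00502) and let-7e (−0.38 ± 0.14, adjusted p = 0.0143), with an adjusted p of 0.418 for the list. In lists of other tissues, 1 of 4 nervous system members rose, miR-9-3-5p (adjusted p = 0.841), and 3 of 4 striated muscle members rose, miR-1 (0.58) and the -p probes of miR-133b (0.56) and miR-208 (0.36), with an adjusted p of 0.501. Counts adjusted over the list alone were the same for each of these lists. The hypoxia miRNA miR-210 (-p probe, 0.45 ± 0.09) and pancreatic miR-375 (-p probe, 0.50 ± 0.14) rose, with too few members tested for a list test. The liver miRNA miR-122a had a value on 12 arrays and was not tested for the mean treatment effect. In the baseline difference of NOS2KO it was tested and did not pass (0.19 ± 0.50, adjusted p = 0.871). In all, 168 of 291 probes passed, 92 higher and 76 lower, against 66 higher and 103 lower as deposited and 66.7% of 189 calls higher after median centring. When the set was a block, 176 passed, 164 of them shared.

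The pairs of treatment effects were compared across probes, which are not independent replicates, with no array shared between genotypes. Changes in WT and p53KO had a Pearson r of 0.808 and a Spearman rho of 0.789 over 293 probes, with 68 probes called in both in the same direction and 0 in opposite ones, against 15.9 by chance for independent lists. The r was 0.779 for NOS2KO and p53KO and 0.685 for WT and NOS2KO. It was 0.461 for p53KO and DKO, 0.424 for WT and DKO and 0.163 for NOS2KO and DKO. For that last pair the Spearman rho was 0.313, 19 probes were called alike against 6.63 by chance, and the r was 0.376 over the common probes and 0.0235 with missing cells at a low value. For WT and DKO 25 probes were called alike and 1 in opposite directions, against 7.1 by chance. Blocking on the set, the r of NOS2KO and DKO was 0.39.

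A response score, chosen after the changes were seen, averaged 65 probes measured on all arrays that WT and p53KO called in the same direction, with falling probes counted negatively. C. parvum changed the score by 1.0 ± 0.11 (SE) in WT and 0.88 ± 0.11 in p53KO, the genotypes used to pick the probes, by 0.72 ± 0.11 in NOS2KO and by 0.36 ± 0.10 in DKO. The response of DKO was smaller than that of NOS2KO, with a difference of −0.36 ± 0.14 (exact permutation p = 0.0144 over 213444 arrangements). The arrangements exchanged arrays across the sets, which differ between the 2 control groups, so this p does not measure the response alone. With the set as a block the difference was −0.33 ± 0.18, within 2 standard errors of 0. The score includes miR-486, whose response in DKO differed from that in WT by −1.49 without passing (adjusted p = 0.0773), and miR-699, for which that difference passed.

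**Figure D3:**
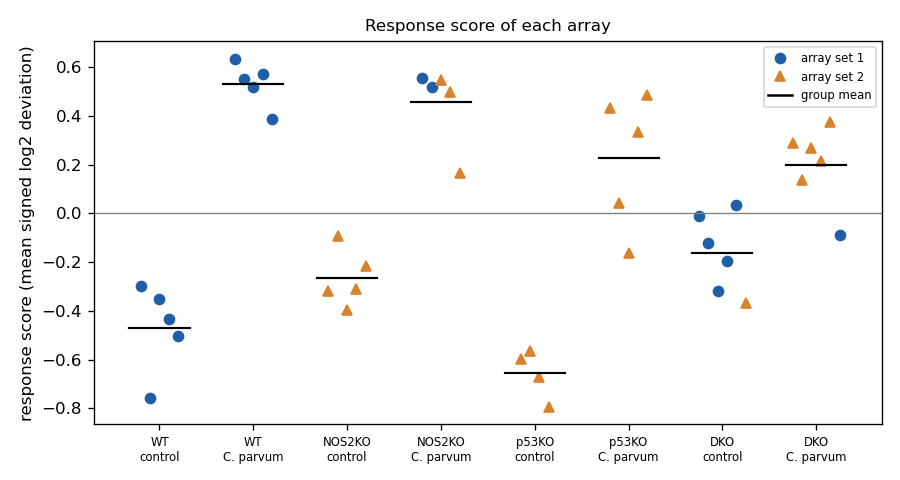
Response score of each array by group, in log2 units. Circles are set 1, triangles set 2, and bars are group means. The mean of treated arrays exceeds that of controls by 1.0 in WT and by 0.36 in DKO.

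The baseline difference of NOS2KO asked what loss of NOS2 changes in saline controls. The let-7 family was higher than in WT in 7 of 8 members and in 8 of 8 adjusted over the list alone (median 0.84, adjusted p = 9.8e-06, and 0.255 with an estimated correlation). let-7f-2 differed by 1.5 ± 0.29 and let-7a-2 by 1.24 ± 0.24 (SE), and let-7f-1 by 1.53. miR-370 (2.98 ± 0.46), miR-429 (1.53), miR-195 (1.39) and the -p probe of miR-221 (1.34) were higher. miR-16-1 (1.04 ± 0.22), miR-451 (1.15 ± 0.33), miR-150 (0.87 ± 0.28) and miR-223 (0.83 ± 0.19) were higher as well. miR-136 (−1.56), miR-32 (−1.39), miR-145 (−0.57) and the -p probes of miR-686 (−4.97 ± 1.28), miR-194-1 (−3.15) and miR-196a-2 (−1.38) were lower. In all, 76 of 329 probes passed, 34 higher and 42 lower. All WT controls belong to set 1 and all NOS2KO controls to set 2, so no comparison within a set exists. Given the set block, estimated from the groups that hold both sets, limma called 0 probes, and 27 had an unadjusted p under 0.05. The differences of miR-429 (−0.33), miR-686 (0.37) and miR-194-1 (0.07) then turned direction, and those of miR-370 (0.59) and let-7f-1 (0.40) shrank. That of the -p probe of miR-221 kept most of its size without passing (1.28 ± 0.44, adjusted p = 0.359). The let-7 list then had a median of 0.08 and an adjusted p of 0.611.

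For p53KO controls the question was what loss of p53 changes without treatment. All 8 let-7 members were higher than in WT, also adjusted over the list alone (median 1.06, adjusted p = 8.03e-08, and 0.0938 with an estimated correlation), with let-7f-2 at 1.70 ± 0.31, let-7e at 1.52 ± 0.35 and let-7a-2 at 1.27 ± 0.25. let-7f-1 (1.98), miR-370 (2.68), miR-429 (1.43), the -p probe of miR-221 (1.48), miR-16-1 (1.08 ± 0.23), miR-150 (1.03 ± 0.30), miR-223 (0.71 ± 0.20) and miR-21 (0.59 ± 0.22) were higher. miR-712-5p (−1.73), miR-291a-5p (−1.31) and the -p probes of miR-543 (−1.65), miR-218-1 (−1.45) and miR-760 (−1.27) were lower. Of 315 probes 84 passed, 46 higher and 38 lower, against 65 higher and 21 lower as deposited and 35 higher and 60 lower after median centring. These groups also share no set. Under a set block, 1 probe passed, the -p probe of miR-543 (13.85 ± 0.56 (SD, n = 4) in p53KO and 15.50 ± 0.44 (SD, n = 5) in WT controls), at −1.37 ± 0.32 (SE, adjusted p = 0.0342), and 33 had an unadjusted p under 0.05. In that fit miR-429 turned direction (−0.43), and miR-370 (0.29) and let-7f-1 (0.85) did not pass. The -p probe of miR-221 kept most of its size but did not pass either (1.42 ± 0.45, adjusted p = 0.245). The let-7 list had a median of 0.34 with the block (adjusted p = 0.0414, and 0.572 with an estimated correlation).

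For DKO controls the question was what loss of both genes changes without treatment, and 5 of the 6 arrays share set 1 with WT. The -p probe of miR-801, which RefSeq lists as U11 spliceosomal RNA, was 9.22 ± 0.76 (SD, n = 5) in WT and 11.01 ± 0.25 (SD, n = 6) in DKO controls, a difference of 1.78 ± 0.26 (SE, adjusted p = 8.82e-06), and 1.80 within set 1. Erythroid miR-451 was higher by 1.74 ± 0.32, at 13.31 ± 0.25 (SD, n = 6), and by 1.58 ± 0.28 with the set as a block. let-7f-1 (1.06 ± 0.27), miR-125a (1.14 ± 0.39), the -p probe of miR-375 (0.87), miR-16-1 (0.70 ± 0.21) and miR-21 (0.59 ± 0.20) were higher. miR-699 was lower by −1.97 ± 0.28, miR-703 by −1.84 ± 0.33, miR-489 by −1.82 ± 0.50, miR-501-5p by −1.39 ± 0.42 and the -p probe of miR-682 by −1.36 ± 0.46. Of the DKO and WT controls, miR-489 had values on 4 and 3, and miR-501-5p on 3 and 4. Their DKO means of 5.19 and 5.64 lay below 5.87, the low value used for missing cells, so these differences rest on few and dim values. With the set as a block miR-125a (1.17), miR-21 (0.51) and the -p probe of miR-682 (−1.26) no longer passed (adjusted p = 0.052, 0.0607 and 0.0694). Their differences kept most of their size, so these lost calls do not point to the set as their source.

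The erythroid list was higher in DKO controls with 1 of 3 members past the threshold and 2 adjusted over the list alone (median 1.02, adjusted p = 0.0336, and 0.219 with an estimated correlation). The let-7 list was higher with 1 of 8 members, let-7f-2 (1.02 ± 0.28), and 3 adjusted over the list alone (median 0.48, adjusted p = 0.0109, and 0.547 with an estimated correlation). Of 343 probes 47 passed, 20 higher and 27 lower. The count was 30 as deposited, 14 with only the arrays compared, 24 with 1 value per miRNA and 84 with another quantile routine. When the set was a block, 39 passed, 35 of them shared, and within set 1 (5 arrays each) 42 passed, 30 of them shared. Without DKO control 1 the count was 19, without DKO control 2 it was 28, and without WT control 2 or 3 it was 31 or 29.

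Among treated mice the knockouts were compared with the same 5 WT arrays, which the 3 comparisons share. NOS2KO differed in 8 of 338 probes, 2 higher and 6 lower. miR-341 was higher by 1.61 ± 0.23 (SE, adjusted p = 6.65e-06, 9.90 ± 0.59 against 8.29 ± 0.34, SD, n = 5 each) and miR-378-3p/422b by 1.11 ± 0.28. miR-136 (−1.15), miR-9-3-5p (−0.97), miR-193 (−0.96), miR-377 (−0.78) and the -p probe of miR-106a (−1.49) were lower. As deposited, 2 were higher and 2 lower, array weights gave 29 calls, and only the arrays compared gave 2. Given the set block, miR-341 alone passed (1.11 ± 0.20, adjusted p = 0.000926), and within set 1 limma called 0 probes, 29 with an unadjusted p under 0.05. With the block miR-378-3p/422b (1.16 ± 0.35), miR-193 (−1.02 ± 0.28) and the -p probe of miR-106a (−1.28 ± 0.38) kept most of their size with wider errors. The differences of miR-136 (−0.66), miR-9-3-5p (−0.68) and miR-377 (−0.46) shrank. The count was 3 or 4 without WT C. parvum 1 or 3, and 15, 17, 4 or 5 without NOS2KO C. parvum 1, 2, 4 or 5.

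For p53KO treated mice miR-341 was higher by 2.07 ± 0.23 (10.36 ± 0.13, SD, n = 5), miR-370 by 2.40 ± 0.46, miR-378-3p/422b by 1.40 ± 0.27, and the -p probes of miR-123 by 1.69 and miR-221 by 1.51. miR-223 (0.77 ± 0.19), miR-16-1 (0.77 ± 0.22) and miR-29b-2 (0.73 ± 0.15) were higher. miR-291a-5p (−1.89), miR-712-5p (−1.53), miR-136 (−1.39) and the -p probes of miR-686 (−4.89 ± 1.27) and miR-218-1 (−1.67) were lower. Of 330 probes 80 passed, 42 higher and 38 lower, against 58 higher and 27 lower as deposited. These groups share no set, and 2 probes passed with the set as a block, among them miR-341 (1.24 ± 0.24, adjusted p = 0.00272). The difference of miR-686 then turned direction (0.46) and that of miR-370 was 0.01.

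For DKO treated mice the -p probe of miR-801 was higher by 2.75 ± 0.26 (SE, a fold of 6.73, adjusted p = 3.42e-10), with 11.74 ± 0.59 (SD, n = 6) against 8.99 ± 0.20 (SD, n = 5), and by 3.13 ± 0.33 with the set as a block. miR-341 was higher by 1.83 ± 0.22, and by 1.13 ± 0.22 with the block. miR-223 (0.92 ± 0.18), miR-34a (0.91 ± 0.31), miR-29b-2 (0.54 ± 0.14), miR-16-1 (0.60 ± 0.21), miR-370 (1.83), miR-199a*-1-3p (1.12) and the -p probe of miR-123 (1.27) were higher. miR-136 (−1.68), miR-291a-5p (−1.60) and the -p probes of miR-686 (−4.75), miR-194-1 (−2.82), miR-491 (−1.31) and miR-34b (−1.18) were lower. Of 343 probes 75 passed, 34 higher and 41 lower, against 55 higher and 26 lower as deposited and 24 higher and 44 lower after median centring. Under a set block, 6 passed, all among the 75, and within set 1 (5 arrays against 1) 22 passed, 13 of them shared. Array weights gave 1.3e+02 calls. miR-370 turned direction in both (−0.16 with the block, −0.24 within set 1), and with the block miR-16-1 (0.01), miR-199a*-1-3p (0.49), miR-123 (0.61), miR-686 (−0.47), miR-194-1 (−0.40), miR-223 (0.47), miR-34a (0.92), miR-29b-2 (0.29), miR-136 (−1.01), miR-291a-5p (−0.75), miR-491 (−1.31) and miR-34b (−0.63) did not pass. Without WT C. parvum 1 the count was 47.

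The interactions asked whether the response to C. parvum depends on the genes. For NOS2KO 1 of 305 probes passed, the -p probe of miR-196a-2, whose treatment effect exceeded that of WT by 1.71 ± 0.37 (SE, adjusted p = 0.015, and 0.0207 with the set as a block). Averaged over the genotypes of the other gene, its difference was 0.98 and did not pass (adjusted p = 0.0551). Counts between 0 and 6 resulted when single arrays were left out, 0 of them without NOS2KO C. parvum 2 6 without WT C. parvum 4 or NOS2KO C. parvum 3, 2 without WT C. parvum 5 or WT control 3 or 4, and 3 without WT control 5. A floor gave 7 calls. For p53KO limma called 0 of 293 probes, and 23 had an unadjusted p under 0.05. The smallest p belonged to the -p probe of miR-532 (−1.02 ± 0.29, adjusted p = 0.345), miR-448 (−1.05 ± 0.39) and miR-297-2 (0.90 ± 0.34), none of which passed. The let-7 list was lower in both interactions, with a median of −0.65 for NOS2KO (0 of 8 members past the threshold, 3 adjusted over the list alone, adjusted p = 0.00024, and 0.645 with an estimated correlation) and −0.54 for p53KO (0 of 8 in both counts, adjusted p = 0.00294, and 0.883 with an estimated correlation). When the set was a block, the list had an adjusted p of 0.0474 for NOS2KO and 0.000382 for p53KO, and of 0.862 and 0.718 with an estimated correlation. For p53KO the block could alter only the spread and not the changes, since each treatment effect lies within a single set. Its value for p53KO is therefore no check on the set.

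For DKO 16 of 312 probes differed in response from WT, 8 up and 8 down. Erythroid miR-451 responded by 1.84 ± 0.45 (SE) less than in WT (difference −1.84, adjusted p = 0.0103). Its level was 11.56 ± 0.38 in WT controls and 13.29 ± 0.35 in treated WT mice (SD, n = 5 each), against 13.31 ± 0.25 and 13.19 ± 0.75 in DKO mice (SD, n = 6 each). miR-699 fell from 10.51 ± 0.27 to 8.27 ± 0.56 in WT, while DKO mice had 8.54 ± 0.35 without and 8.37 ± 0.49 with treatment, a difference of responses of 2.07 ± 0.40 (adjusted p = 0.00239). miR-703 had 10.88 without and 9.13 with treatment in WT, and 9.04 and 9.17 in DKO mice (difference 1.88 ± 0.46). miR-378-3p/422b (1.65 ± 0.37), miR-138 (1.38 ± 0.36) and miR-341 (1.31 ± 0.31) had higher responses in DKO, and miR-412 (−2.41 ± 0.58), miR-448 (−1.39 ± 0.37), miR-7-2 (−1.34 ± 0.31) and the -p probe of miR-375 (−1.43 ± 0.39) lower ones. The split was 19 up and 8 down as deposited and 6 up and 13 down after median centring. With the set as a block 11 passed, 7 of them shared, including miR-451, miR-699, miR-703, miR-378-3p/422b, miR-448 and miR-7-2. With the probes of each miRNA averaged 7 passed and miR-7-2 turned direction (0.082), and array weights gave 57 calls and a floor 26. Within set 1 (5, 5, 5 and 1 arrays) 36 passed, 8 of them shared. Without WT control 1 the count was 34, and without DKO control 6 it was 29.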

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

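All tests of explanations in this part, and the splits of the arrays, were chosen after the results they measure had been seen. Of 228 tests for an array far from the others of its group, 23 passed. Chance flags about 1 in 20 groups.

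The arrays that stood apart do so mostly in a few samples. NOS2KO C. parvum 5 lay below its group in response score (0.164), in the mean of the lymphoid list (11.76), and in miR-486 (13.44) and the -p probes of miR-671 (7.13) and miR-221 (7.71), and above it in the -p probe of miR-297b (9.20). DKO control 6 lay above the other DKO controls in miR-370 (11.31) and the -p probes of miR-326 (8.56) and miR-687 (7.85), and below them in that of miR-686 (6.66). DKO C. parvum 6 lay apart in the other direction in miR-370 (9.08) and the -p probe of miR-686 (11.97), and also in its let-7 mean (10.90) and its median as deposited (10.23). The sets were defined by miR-370, and the -p probe of miR-686 separates them without overlap. The flags of these probes therefore restate the set of both arrays and are not independent of each other. WT control 2 had 310 measured probes and a stromal mean of 9.96. NOS2KO control 5 had a myeloid mean of 13.11. WT C. parvum 5 had 12.68 for miR-451 and 11.72 for miR-145, on the control side of its group. NOS2KO control 2 had 8.68 for the -p probe of miR-123 and 9.10 for miR-199a*-1-3p. p53KO control 1 (11.90) and p53KO C. parvum 3 (11.90) lay apart in miR-486, above and below their groups, and the equal values are equal ranks after quantile normalization.

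Responses to C. parvum that differed from WT were those of the -p probe of miR-196a-2 in NOS2KO (1.71) and of 16 probes in DKO. In DKO the differences were −1.84 for miR-451, 2.07 for miR-699, 1.88 for miR-703, 1.65 for miR-378-3p/422b, 1.43 for miR-138-2, 1.38 for miR-138, 1.31 for miR-341, 0.74 for miR-679 and 0.92 for the -p probe of miR-28. They were −2.41 for miR-412, −1.39 for miR-448, −1.34 for miR-7-2, −1.05 for miR-27a, and −1.43, −1.22 and −0.80 for the -p probes of miR-375, miR-181a-2 and miR-24-2. Each is a test of the difference itself. Of the 16, 7 passed with the set as a block, and among those that did not were miR-412 (−1.49, adjusted p = 0.0695), miR-341 (0.75, adjusted p = 0.0695), miR-138 (1.14, adjusted p = 0.0695) and miR-375 (−1.08, adjusted p = 0.1).

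The baseline differences of NOS2KO and p53KO follow the array sets. Of 76 called probes in NOS2KO controls, 72 differed in the same direction between the sets inside the groups that hold both, and 78 of 84 did in p53KO controls. As many were reached by 4 of 360 arrangements of the set labels (exact p = 0.0111 in both). The difference between the sets inside groups rests on the arrays outnumbered there, NOS2KO C. parvum 1 and 2, DKO control 6 and DKO C. parvum 6. The label of DKO C. parvum 6 may be wrong, and the fits with the set as a block share this limit. With the set as a block the median size of the called changes went from 0.88 to 0.41 in NOS2KO and to 0.43 in p53KO, while their standard errors rose from 0.23 to 0.28 and from 0.24 to 0.30, so the calls ended by smaller changes and wider errors. A batch of arrays is a candidate explanation, and since a median share of 0.514 of the p53KO changes was kept with the block, an effect of the genotype cannot be told apart from it with no set shared by both groups.

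The response score was smaller in DKO than in NOS2KO, and with the set as a block the difference was −0.332 ± 0.181, within 2 standard errors of 0, so the set stays open as a contribution. Without DKO C. parvum 6, whose label may be wrong, the difference was −0.303 ± 0.141, little more than 2 standard errors below 0. This argues against a wrong label of that array as the whole cause but does not exclude it, and the fit had no block for the set. A swap of DKO control 6 with it is argued against by the score of that control, −0.366, below the other DKO controls, which reached 0.0331. DKO C. parvum 6 itself scored −0.0907, below the other treated DKO arrays (0.137 to 0.376) and inside the range of the DKO controls, so a wrong label of that array alone stays open as a part of the difference. A dependence on both genes stays a hypothesis, since the comparison was chosen after the responses were seen and the set stays open.

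Probes ending in -p moved up relative to those ending in -a in the mean treatment effect, with medians of 0.20 and −0.00 (a gap of 0.206 ± 0.073). The gap was 0.199 ± 0.070 on the values as deposited, nearly unchanged, which argues against the quantile normalization as its cause. Among brighter probes it was 0.424 ± 0.130, not smaller, which argues against dim probes. These gaps compare medians over probes, 202 ending in -a and 86 in -p in the main setting. Probes are not independent replicates, and the gap was not tested over mice. What the endings mean is not given in the sources used here, so a difference in probe chemistry may also produce the gap. No biological explanation was tested.

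Other splits of the same arrays into groups of the same sizes, 100 for each comparison with the real one included, show how often a random grouping calls as many probes. Nothing was adjusted over the comparisons, and the drawn splits can miss one that calls more. The real count was not reached by another drawn split for the treatment effects in WT (110 real, 62 highest other), NOS2KO (89 and 63) and on average (168 and 79), which argues against chance. For DKO (53 and 25) the drawn splits missed a split that called more, given at the end of this paragraph. In p53KO 2 splits reached the real count of 94 or more, the real one included, with 99 the highest other. As many calls were thus rare among the drawn splits, but a random grouping of these arrays can call more. Only the real split of the 100 reached the count for the baseline differences of NOS2KO (76 and 40), p53KO (84 and 65) and DKO (47 and 25). The same held for the treated differences (8 and 7, 80 and 17, 75 and 24) and for the interaction of DKO (16 and 8). For treated NOS2KO the counts of 8 and 7 lie close, and the real one ran from 3 to 17 when single arrays were left out. These splits ignore the array set, which coincides with or overlaps these groups, so they do not exclude the set. The baseline differences with the set as a block had 0 (limma, 27 at an unadjusted p under 0.05), 1 and 39 calls, the treated differences 1, 2 and 6, and the interaction of DKO 11. Chance cannot be excluded for the interaction of NOS2KO, where 14 splits had at least the 1 real call (54 highest other). For that of p53KO the splits decide nothing, since each of the 100 reaches its 0 calls (4 highest other, 23 real probes at an unadjusted p under 0.05 in limma). A split of the 12 DKO arrays by set, not among those drawn, called 54 probes against 53 for the real groups, and with the set as a block 11 passed. A grouping that follows the set is therefore not excluded for the treatment effect in DKO.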

How the results depend on the processing

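Tests with the array set, the low value for missing cells, the 227 common probes, another quantile routine and the pair of arrays that stand apart were chosen after the data were seen. Of the called changes of named miRNAs, 33 lost the call as deposited, 27 with median centring, 21 with the floor, 2 with array weights and 24 with only the arrays compared, with the direction kept in each. With 1 value per miRNA 50 lost the call and 1 reversed, and with the set as a block 79 lost it and 8 reversed. The call of miR-196a-2 in the interaction of NOS2KO was lost when averaged over the other gene (0.98). With the replicate number as a block, 207 kept both and 8 lost the call. The numbers do not pair the arrays, since 4 of 20 pairs of a control and a treated array with the same number had a correlation above 0.1 (−0.408 to 0.302, median −0.146), and no paired analysis is given beside this block. Where not stated otherwise, the cause was not tested.

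With 1 value per miRNA fewer items are tested, and the calls were 64 (WT), 47 (NOS2KO), 52 (p53KO) and 34 (DKO) for treatment, 54 (p53KO) and 24 (DKO) at baseline, 51 (p53KO) and 39 (DKO) among treated mice, and 0 (NOS2KO) and 7 (DKO) for interactions. There limma called none of the NOS2KO interactions. The direction reversed for miR-451 in DKO (0.24) and for miR-7-2 in the interaction of DKO (0.082). With only the arrays compared the calls were 47 for treatment in NOS2KO, 14 at baseline in DKO and 2 in treated NOS2KO. As deposited they were 27 for treatment in DKO, 30 at baseline in DKO, 4 in treated NOS2KO and 27 for the interaction of DKO. Array weights gave 129 for treatment in DKO, 29 in treated NOS2KO, 1.3e+02 in treated DKO, 2 for the interaction of NOS2KO and 57 for that of DKO, and miR-451 in DKO was 0.16. Median centring gave 2 for the interaction of NOS2KO, and miR-155 in DKO was 0.030. The floor gave 7 and 26 for the interactions of NOS2KO and DKO, miR-34a in NOS2KO was 0.086 and the similarity of p53KO and DKO was 0.571. The estimated correlation left 0 of 13 list calls.

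With the set as a block 11 passed for treatment in DKO, 0 and 1 at baseline in NOS2KO and p53KO, 1, 2 and 6 in treated NOS2KO, p53KO and DKO, 3 for the interaction of NOS2KO, and the similarity of NOS2KO and DKO was 0.39. Reversed were, for treatment in DKO, miR-429 (−0.11), the -p probe of miR-686 (0.20) and miR-155 (0.046), at baseline miR-429 (−0.33 in NOS2KO, −0.43 in p53KO), miR-686 (0.37) and miR-194-1 (0.070) in NOS2KO, and in treated mice miR-686 in p53KO (0.46) and miR-370 in DKO (−0.16). Within set 2 the calls were 59 for treatment in NOS2KO and 2 in DKO, with miR-687 (−0.095), miR-429 (−0.11) and miR-451 (0.045) reversed in DKO. Within set 1 they were 1 for treatment in DKO, 0 in treated NOS2KO, 22 in treated DKO and 36 for the interaction of DKO. Reversed there were miR-686 (0.91), miR-203 (0.020), miR-34a (0.044) and miR-155 (0.42) for treatment in DKO, and miR-370 (−0.24), miR-686 (0.088) and miR-16-1 (−0.15) in treated DKO. A lone array of a set is assumed to vary like the other groups. Fits within a set exist only where it holds arrays of each group compared.

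The other quantile routine gave 84 at baseline in DKO, 3 in treated NOS2KO and 2 for the interaction of NOS2KO. The common probes gave 5 in treated NOS2KO, 4 for the interaction of NOS2KO, and similarities of 0.556 (WT and DKO), 0.376 (NOS2KO and DKO) and 0.589 (p53KO and DKO). Missing cells at the low value gave 0.272, 0.0235 and 0.331 for the same pairs and 0.665 for NOS2KO and p53KO. Leaving out the 2 arrays that stand apart gave 31 at baseline in DKO and 4 in treated NOS2KO.

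Leaving out 1 array at a time gave, for treatment, 94 to 111 (WT), 65 to 115 (NOS2KO), 62 to 114 (p53KO), 26 to 61 (DKO) and at least 160 (mean). At baseline it gave 54 to 83 (NOS2KO), 64 to 86 (p53KO) and 19 to 59 (DKO), in treated mice 3 to 17, 57 to 82 and 47 to 74, and for interactions 0 to 6, 0 to 0 and 14 to 34. Counts moved by more than 1.5 times without p53KO C. parvum 1 (62), and in DKO without controls 3 (26) or 4 (27) or C. parvum 2 (31) or 5 (35). At baseline in DKO they did so without DKO control 1 (19) or 2 (28) or WT control 3 (29) or 2 (31), in treated DKO without WT C. parvum 1 (47), and for the interaction of DKO without WT control 1 (34) or DKO control 6 (29). In treated NOS2KO mice they did so without WT C. parvum 1 (3) or 3 (4) or NOS2KO C. parvum 1 (15), 2 (17), 4 (4) or 5 (5), and for the interaction of NOS2KO without WT control 3 (2), 4 (2) or 5 (3), WT C. parvum 4 (6) or 5 (2), or NOS2KO C. parvum 2 (0) or 3 (6). In DKO miR-155 ranged from −0.17 without C. parvum 6 to 0.0061 without C. parvum 1, and miR-451 from −0.22 without C. parvum 1 to 0.18 without C. parvum 6. Probes of other organisms were not run as an alternative, since all are of mouse.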

Other observations

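Whether a probe had a value at all was compared between control and treated arrays by an exact conditional test stratified by genotype for 234 probes, those with 4 to 37 measured arrays, a test chosen after the data were seen. miR-204, which is typical of epithelial and neural cells, had a value on 11 of 20 control and 0 of 21 treated arrays (adjusted p = 0.0167), with values in 2 of 5 WT, 2 of 5 NOS2KO, 3 of 4 p53KO and 4 of 6 DKO controls. Erythroid miR-144 had a value on 0 of 5 WT controls and 5 of 5 treated WT arrays, and on 13 of 20 control and 21 of 21 treated arrays in all (adjusted p = 0.103), and did not pass. In WT, where miR-144 could not be tested for change, erythroid miR-451 and miR-486 rose.

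The let-7 mean followed the set inside groups. Among treated NOS2KO mice it was 10.78 ± 0.10 (SD, n = 2) on set 1 and 11.82 ± 0.16 (SD, n = 3) on set 2, and DKO control 6 had 12.10 against 11.43 ± 0.31 (SD, n = 5) for the other DKO controls. Of 54 miRNAs with both kinds of probe, the changes of the -a and the -p probe had a Pearson r of −0.039, with 8 pairs called in the same and 12 in opposite directions. For miR-221 the -a probe rose by 0.60 and the -p probe fell by 0.57, and for miR-24-2 the -p probe rose by 0.50 on average.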
